A study of Arabidopsis thaliana with 6 samples.

How the data were processed

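Polyadenylated RNA from 21-day-old Arabidopsis thaliana plants of the Columbia ecotype, grown on MS medium, was sequenced from vegetative tissue after a stranded Illumina mRNA library preparation, per the labels' protocols. The series holds 6 libraries in 2 groups of 3 biological replicates, wild-type and the ucp1 ucp3 double mutant. UCP1 and UCP3 encode members of the mitochondrial uncoupling protein family, carriers of the inner mitochondrial membrane. No batch, plate or harvest date is given in the sources used here, and nothing beyond the words "biological replicate" says how the 3 samples of a group were separated.

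The deposited tables give estimated counts and TPM values per transcript model. The submitters' processing notes name kallisto, DESeq2 and the TAIR10 build, without versions. Neither the strand setting of the quantification nor its transcript index is given in the sources used here. Reads of a gene and of a gene overlapping it on the other strand were therefore treated as not separable. TPM values deposited by the authors were used only for organelle shares and for average transcript lengths.

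Estimated counts of 35386 transcript models were summed to 27416 genes and rounded to whole numbers. Of these genes, 26719 matched a locus of the TAIR10.1 RefSeq annotation, which was used for names, mRNA sequences and the order of loci. Its coordinates are not printed, because the submitters' processing notes name TAIR10. Totals per library were 4813549, 3497081 and 4236329 reads in wild-type replicates 1 to 3, and 4484787, 11296137 and 1183612 reads in ucp1 ucp3 replicates 1 to 3. A count of 3, used as the detection floor, corresponds to 0.264 CPM in the deepest library and 2.71 CPM in the shallowest. Floors cover counting error only. The intervals given for fold changes rest on the standard errors of the test described below, so they also include variation between replicates. Replicates of a group differed by more than sampling noise in every pair, with chi-square over degrees of freedom between 2.50 and 6.70 across genes, so none was treated as a duplicate.

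Genes were tested with edgeR 4.0.16 in R 4.3.3, using the default expression filter, TMM normalisation and the robust quasi-likelihood F test with genotype as the only term. The filter kept 17415 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. CPM values are counts over the TMM-scaled library size and are the normalised levels given for each gene. Standard errors of log2 fold changes were taken as the estimate over the square root of its F statistic, and fold changes are the group labelled ucp1 ucp3 over wild-type.

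Before the data were examined, 30 gene lists, the rule for named genes and the alternatives were fixed; 2 lists of organelle-encoded genes were taken by locus prefix. Lists with at least 3 tested members, 30 in all, were tested with camera from limma 3.58.1 at its preset correlation of 0.01, two-sided, adjusted over the lists, and again with an estimated correlation. Counts of members are given over all tested genes and adjusted over the list alone. The rule names UCP1, UCP2, UCP3, DIC1, DIC2 and DIC3, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM and groups that did not overlap, and up to 4 members of each list, those past the threshold by size and then those with the smallest p. List members named beyond it, among them BCAT2, TPS11, JAZ9, MYC2, LOX2, PDF1.2A, RBCS1B, mtHSC70-1, HRA1, MYB28, MYB51, mMDH1, ORE1 and CAT3, were chosen after their values were seen. Sequences shared with other genes were counted as 31-mers of the annotated mRNAs, on the same and on the opposite strand. Shares of reads were compared with exact two-sided permutation tests.

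The procedure was tested on counts simulated from the real means, library sizes and dispersions. With 200 changed genes seeded before the filter and 17197 genes entering the test, the comparison of the groups recovered 31.8% of the genes changed 1.5-fold, 82.5% of those changed 2-fold and 100% of those changed 4-fold, with 16 false calls among 156. With no changed gene, 2 of 17199 genes were called. For the list test, 30 unchanged lists gave 0 calls, and a list of 15 genes raised by 0.50 on the log2 scale had an adjusted p of 2.5e-09 with the preset and 0.0701 with an estimated correlation. Simulated genes were drawn independently of each other, so this does not test the preset on lists whose genes vary together. A gene had the same dispersion in all simulated libraries, and no library was set apart from its group. Recovery and false calls can therefore differ in the real data. In the real data the estimated correlation was 0.23 for the sugar starvation list, 0.53 for the jasmonate list and 0.62 for the light-harvesting list.

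The alternatives were a replicate block, DESeq2 1.42.0, limma-voom on unrounded estimates, RLE size factors, library totals without TMM, no filter, a filter at 1 CPM in at least 3 libraries, removal of organelle loci, an offset for average transcript length, and each library left out in turn. Thinning all libraries to the depth of the shallowest was added after the data were examined. Pseudocount alternatives fixed for normalised units were not needed, since the deposited values are estimated counts. Values of single transcript models were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.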

Results

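The transcriptomes of wild-type Columbia plants and of plants labelled as the ucp1 ucp3 double mutant were compared in 3 libraries each, to ask which transcripts differ when 2 mitochondrial uncoupling protein genes carry mutations. The libraries held between 1183612 and 11296137 reads assigned to genes, a 9.54-fold range. Replicate 3 of the libraries labelled ucp1 ucp3 was the shallowest and also lay apart from the other 5 on the first principal component of log2 CPM, at 59.3 against -28.8 to 9.42. That component held 47.0% of the variance.

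UCP1 and UCP3 transcripts were present in every library of both groups. UCP1 (AT3G54110, on chromosome 3) had a mean of 70.6 ± 4.18 CPM in wild-type (SD, n = 3) and 55.7 ± 10.5 CPM in the libraries labelled ucp1 ucp3. The separate UCP1 values were 69.2, 67.3 and 75.3 CPM in wild-type and 67.2, 46.6 and 53.3 CPM in the labelled mutants, from 59 to 530 reads per library. UCP3 (AT1G14140, on chromosome 1) had 12.3, 16.1 and 13.0 CPM in wild-type and 8.68, 10.2 and 10.8 CPM in the labelled mutants, from 12 to 116 reads per library.

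**Figure D1:**
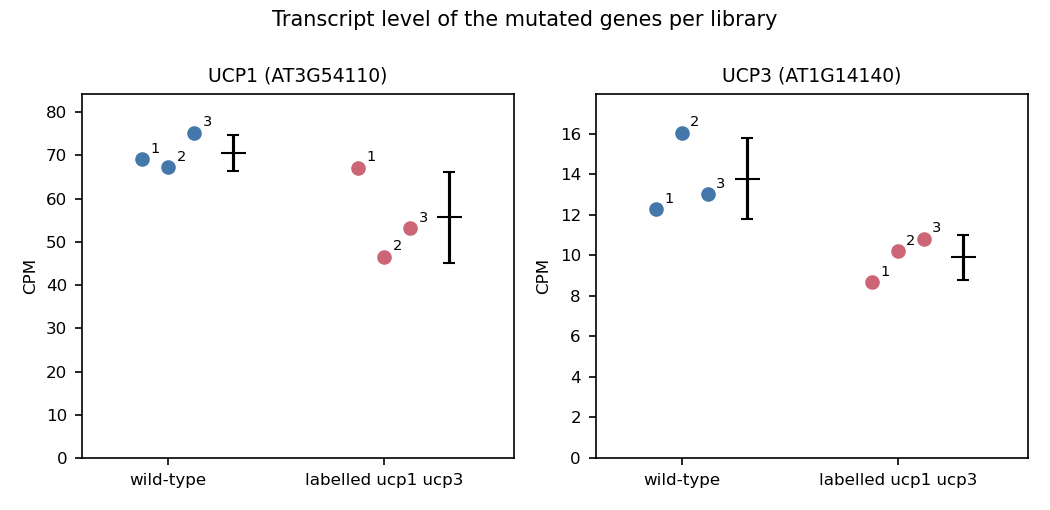
Normalised level (CPM, linear axis from 0) of UCP1 and UCP3 in each library, with the replicate number beside each point and the group mean and SD as a bar (3 libraries per group). UCP1 lies between 46.6 and 75.3 CPM in all 6 libraries, and UCP3 between 8.68 and 16.1 CPM.

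Neither difference passed the test over all genes. The log2 fold change of UCP1 was -0.35 (95% interval -0.65 to -0.05), with an edgeR adjusted p of 0.226, and that of UCP3 was -0.49 (-0.90 to -0.07), with an edgeR adjusted p of 0.224. The intervals place the level of UCP1 in the labelled mutants between 63.8% and 96.6% of wild-type and that of UCP3 between 53.4% and 95.2%. Because the targeted transcripts do not check the labels, the group is called the libraries labelled ucp1 ucp3, or the labelled mutants, and every direction below rests on the labels. Of the other family members, DIC1, a mitochondrial dicarboxylate carrier, had a log2 fold change of -0.60 (edgeR adjusted p = 0.0904), DIC2 of -0.21 and UCP2, with 27.6% of its 31-mers on the opposite strand of other genes, of -0.14, and DIC3 had 0 or 1 read per library and was not tested. Adjusted over the list alone, UCP1, UCP3 and DIC1 were lower (3 of 5 tested). The family list was called lower by camera (adjusted p = 0.0496; adjusted p = 0.546 with an estimated correlation), and 9 of 16 alternatives ended that call.

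Among the 12 largest rises were those of ASN1, the dark-inducible asparagine synthetase gene, and of genes of jasmonate signalling. ASN1 (AT3G47340) went from 79.5 ± 26.6 to 622 ± 176 CPM in the libraries labelled ucp1 ucp3, a 7.79-fold rise (SD, n = 3). The jasmonate repressor gene JAZ10 rose 6.02-fold, from 2.34 ± 0.823 to 15.8 ± 6.17 CPM, and JAZ7 6.56-fold from at most 1.11 CPM in each wild-type library. ILL6, an amidohydrolase that acts on jasmonate conjugates, rose 4.89-fold, and HAK5, a high-affinity potassium transporter, 3.90-fold. The smallest p of all genes was that of SPPA (AT1G73990), a plastid signal peptide peptidase gene, which fell from 53.1 ± 5.57 to 18.4 ± 1.32 CPM.

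In all, 136 genes were higher and 84 were lower in the libraries labelled ucp1 ucp3 (edgeR quasi-likelihood test, adjusted p under 0.05), of 17415 tested. At least 2-fold, 48 were higher and 24 lower. The groups did not overlap in any of the 220 called genes, and they did not overlap in 4105 of all tested genes, where chance gives 10%. The called changes had a median size of 1.82-fold, and on simulated data 16 of 156 calls were false. Scaling by library totals alone divided the calls into 109 higher and 110 lower. The number of calls depended on each library: 31 higher and 22 lower without wild-type replicate 1, 126 and 136 without wild-type replicate 2, 100 and 44 without wild-type replicate 3, 46 and 16 without ucp1 ucp3 replicate 1, 326 and 347 without ucp1 ucp3 replicate 2, and 54 and 19 without ucp1 ucp3 replicate 3.

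**Figure D2:**
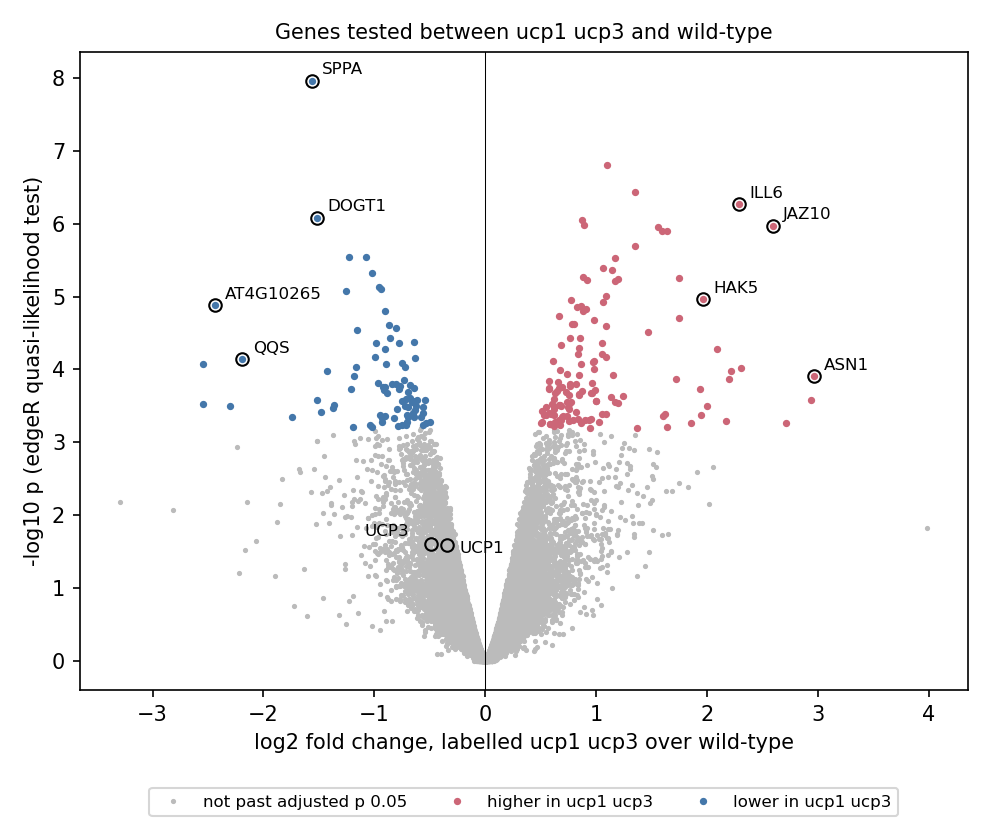
Log2 fold change (horizontal axis, libraries labelled ucp1 ucp3 over wild-type) against -log10 of the unadjusted edgeR p (vertical axis) for each of the 17415 tested genes, with the 136 called higher and the 84 called lower in colour. SPPA has the smallest p, and UCP1 and UCP3 lie among the genes that did not pass.

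Among the other genes with the largest rises, AT2G47880, annotated as a glutaredoxin family protein, rose 7.66-fold from 2.40 ± 1.55 CPM. The aquaporin family gene NIP2;1 rose by 2.31 on the log2 scale, the uncharacterised AT3G43850 by 2.22, the protein kinase gene AT1G33770 by 2.19 and the cell wall enzyme gene XTH25 by 2.17. PMAT2, an acyltransferase gene, rose by 2.09 and GSTU25, a glutathione transferase gene, by 2.00. Their edgeR adjusted p-values lay between 0.0161 for PMAT2 and 0.0450 for XTH25. Assignment is uncertain for 3 of these, since 57.2% of the 31-mers of NIP2;1, 33.0% of those of AT2G47880 and 22.3% of those of AT1G33770 occur on the opposite strand of another gene's mRNA. JAZ7, NIP2;1, AT3G43850, AT1G33770, XTH25 and PMAT2, at 2.49 CPM or less in each wild-type library, stood near the counting floor of the wild-type libraries (0.614 to 0.831 CPM). Under it lay JAZ7 (0.232 CPM) and AT3G43850 (0.465 CPM) in wild-type replicate 3 and NIP2;1 (0.554 CPM) in wild-type replicate 2. The sizes of these 3 rises are therefore uncertain.

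SPPA had a log2 fold change of -1.57 ± 0.14 (SE; edgeR adjusted p = 0.000191) and lay between 17.4 and 19.9 CPM in the 3 labelled mutants, against 49.9 to 59.6 CPM in wild-type. The glucosyltransferase gene DOGT1 had values as tight, at 18.1 ± 0.935 CPM in wild-type and 6.56 ± 0.595 CPM in the labelled mutants (edgeR adjusted p = 0.002), although 16.9% of its 31-mers occur in other genes on the same strand and 14.2% on the opposite strand. QQS, an orphan gene linked to leaf starch content, dropped from 36.4 ± 4.47 to 6.25 ± 4.34 CPM, and ACS7, which encodes an ethylene biosynthesis enzyme, from 31.6 ± 8.35 to 9.18 ± 4.04 CPM. ARCK1, a receptor-like kinase gene, had a log2 fold change of -1.52.

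The remaining falls were in genes at low levels. The cupin family gene AT4G36700 had a log2 fold change of -2.55, and like AT4G10265 it had 0 reads in ucp1 ucp3 replicate 3, where the floor was 2.71 CPM. In that library ARCK1, AT2G41231, AT2G30766, AT1G21320 and AT5G44390 also lay under the floor. The uncharacterised AT2G41231 had -2.54, the wound-responsive family gene AT4G10265 -2.44 and AT2G30766, which encodes a peptide of the iron-regulatory IRON MAN family, -2.30. AT1G21320 had -1.48, AT5G44390, of the berberine bridge enzyme family, -1.43 and AT1G23205, of the pectin methylesterase inhibitor family, -1.37. Opposite-strand sequence of other genes covers 63.4% of the 31-mers of AT2G41231 and 17.5% of those of AT2G30766, and 18.7% of those of AT1G21320 are shared on the same strand. Of the 24 genes named by the size of change, JAZ10, ILL6, SPPA, DOGT1 and AT4G10265 were called in every alternative that tested them. The other 19 lost the call in at least 1, with 17 lost without wild-type replicate 1, 16 without ucp1 ucp3 replicate 3 and 14 without ucp1 ucp3 replicate 1. ASN1 lost it without ucp1 ucp3 replicate 1 and without replicate 3 of that group.

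**Figure D3:**
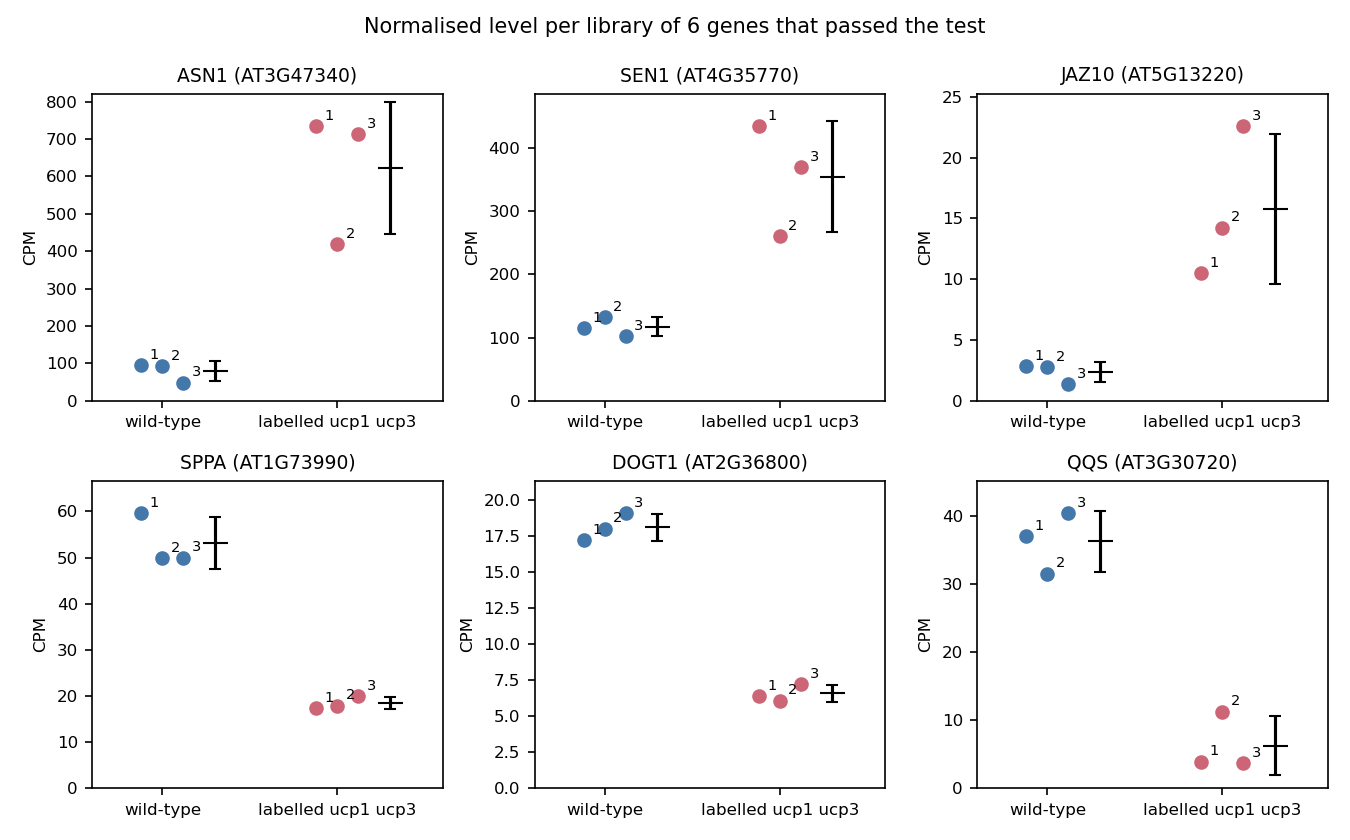
Normalised level (CPM, linear axes from 0) of ASN1, SEN1, JAZ10, SPPA, DOGT1 and QQS in each library, with the replicate number beside each point and the group mean and SD as a bar (3 libraries per group). The groups do not overlap in any of the 6 genes, and SPPA lies between 17.4 and 19.9 CPM in the libraries labelled ucp1 ucp3.

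Genes induced by sugar starvation and of branched-chain amino acid breakdown were higher as a list in the libraries labelled ucp1 ucp3. Of 15 tested members, 4 rose, 0 fell and 11 did not pass. The number that rose depended on single libraries: 1 of 16 without ucp1 ucp3 replicate 1 and 1 of 16 without replicate 3 of that group, but 9 of 16 without its replicate 2. Besides ASN1, those that rose with all 6 libraries were SEN1, a dark-induced gene (117 ± 14.9 to 355 ± 87.6 CPM; log2 fold change 1.59), MCCA, which encodes a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown (81.4 ± 23.2 to 169 ± 22.7 CPM; 1.05), and the dark-inducible DIN11 (1.00). Adjusted over the list alone, 10 were higher, among them BCAT2 (1.55) and TPS11 (1.25). The list's median log2 fold change was 0.45, and camera called it higher (adjusted p = 4.8e-08; adjusted p = 0.546 with an estimated correlation).

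In the jasmonate response list, 4 of 16 tested members rose and 0 fell. Without wild-type replicate 1, 1 of 17 rose, and without wild-type replicate 3, 2 rose and 1 fell; 1 also fell without wild-type replicate 2, with the replicate block, with DESeq2 and after thinning, which gave 6 that rose. With all 6 libraries, JAZ7 and JAZ10 were joined by JAZ2 (log2 fold change 1.13) and by OPR3, an enzyme gene of jasmonate synthesis (27.2 ± 2.14 to 80.5 ± 29.7 CPM). Adjusted over the list alone, 10 were higher, including JAZ9 (log2 fold change 1.83) and MYC2 (1.22), and 2 were lower, LOX2 (-1.03) and PDF1.2A (-0.91). The library labelled ucp1 ucp3 replicate 3, which lay apart on the first component, had the highest level of JAZ2, JAZ7, JAZ9, JAZ10, MYC2 and OPR3. Assignment is uncertain for MYC2, since 98.5% of its 31-mers occur on the opposite strand of another gene's mRNA, and for PDF1.2A, which shares 10.4% with other genes. LOX2 encodes a chloroplast lipoxygenase of jasmonate synthesis, and PDF1.2A a defensin. The median was 1.11, and camera called the list higher (adjusted p = 2.7e-07; adjusted p = 0.571 with an estimated correlation).

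The list of light-harvesting and Rubisco genes was called higher by camera (adjusted p = 2.3e-06; adjusted p = 0.775 with an estimated correlation), with a median log2 fold change of 0.49 over 19 members, which fell to 0.315 without ucp1 ucp3 replicate 3. The antenna gene LHCB1.3 rose (log2 fold change 0.72; edgeR adjusted p = 0.0320), and the other 18 members did not pass over all genes; 32.1% of its 31-mers are shared with close copies. Without ucp1 ucp3 replicate 2, 9 of 19 rose, and 0 rose when any other library was left out; DESeq2 gave 10, no filter 7 and thinning 5. The list fixed beforehand does not hold the antenna genes LHB1B1 (1.55) and LHB1B2 (0.97), which were also called, with uncertain reads. Adjusted over the list alone, 11 were higher and 1, RBCS1B, was lower; RBCS1B shares 18.9% of its 31-mers with other genes. The 14 antenna genes of the list had a median of 0.55 and the 4 Rubisco small subunit genes a median of 0.08, from -0.33 to 0.13.

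Camera called 4 further lists. Abscisic acid, drought and cold response genes were higher as a list (median 0.30, adjusted p = 0.0166; adjusted p = 0.571 with an estimated correlation), with 0 of 11 members past the test over all genes (2 without ucp1 ucp3 replicate 2) and 4 higher adjusted over the list alone, among them RAB18 (1.48) and COR15B (0.89), the latter with 28.2% of its 31-mers on the opposite strand of another gene. Leaving out 1 library moved this median between 0.114 (without ucp1 ucp3 replicate 1) and 0.547 (without wild-type replicate 2), that of the cell division list between 0.161 and 0.478 and that of the plastid list between 0.206 and 0.559. Cell division genes had 6 of 6 estimates above 0 and a median of 0.33, with 0 past either test (adjusted p = 0.0166; adjusted p = 0.546 with an estimated correlation). Plastid-encoded genes had a median of 0.36 over 21 members, with 0 past either test (adjusted p = 0.0166; adjusted p = 0.786 with an estimated correlation). Heat shock and chaperonin genes were lower as a list (median -0.45, adjusted p = 0.00386; adjusted p = 0.546 with an estimated correlation). In that list mtHSC70-2, a mitochondrial chaperone gene, fell (68.4 ± 4.75 to 46.0 ± 5.14 CPM; 19.0% of its 31-mers are shared; 3 members fell without ucp1 ucp3 replicate 2 and 0 without any other library), and HSP60 (-0.43), HSP18.2 (-1.45), HSP90.1 (-0.91) and mtHSC70-1 (-0.40) were lower adjusted over the list alone.

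Of 30 lists tested, 8 were called with the preset correlation and 0 with an estimated one. A simulated list of 15 genes raised by 0.50 on the log2 scale also missed the call with an estimated correlation (camera adjusted p = 0.0701). A missing call under that setting therefore does not decide against a rise. Every other grouping of the 6 libraries into 3 and 3 also gave called lists at the preset correlation, from 2 to 10. The abscisic acid list lost its call without the filter and with the stricter filter. The plastid list lost it in those fits, without wild-type replicate 2, without ucp1 ucp3 replicate 1 and after thinning, and the cell division list without wild-type replicate 3, without ucp1 ucp3 replicate 2 and after thinning.

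**Figure D4:**
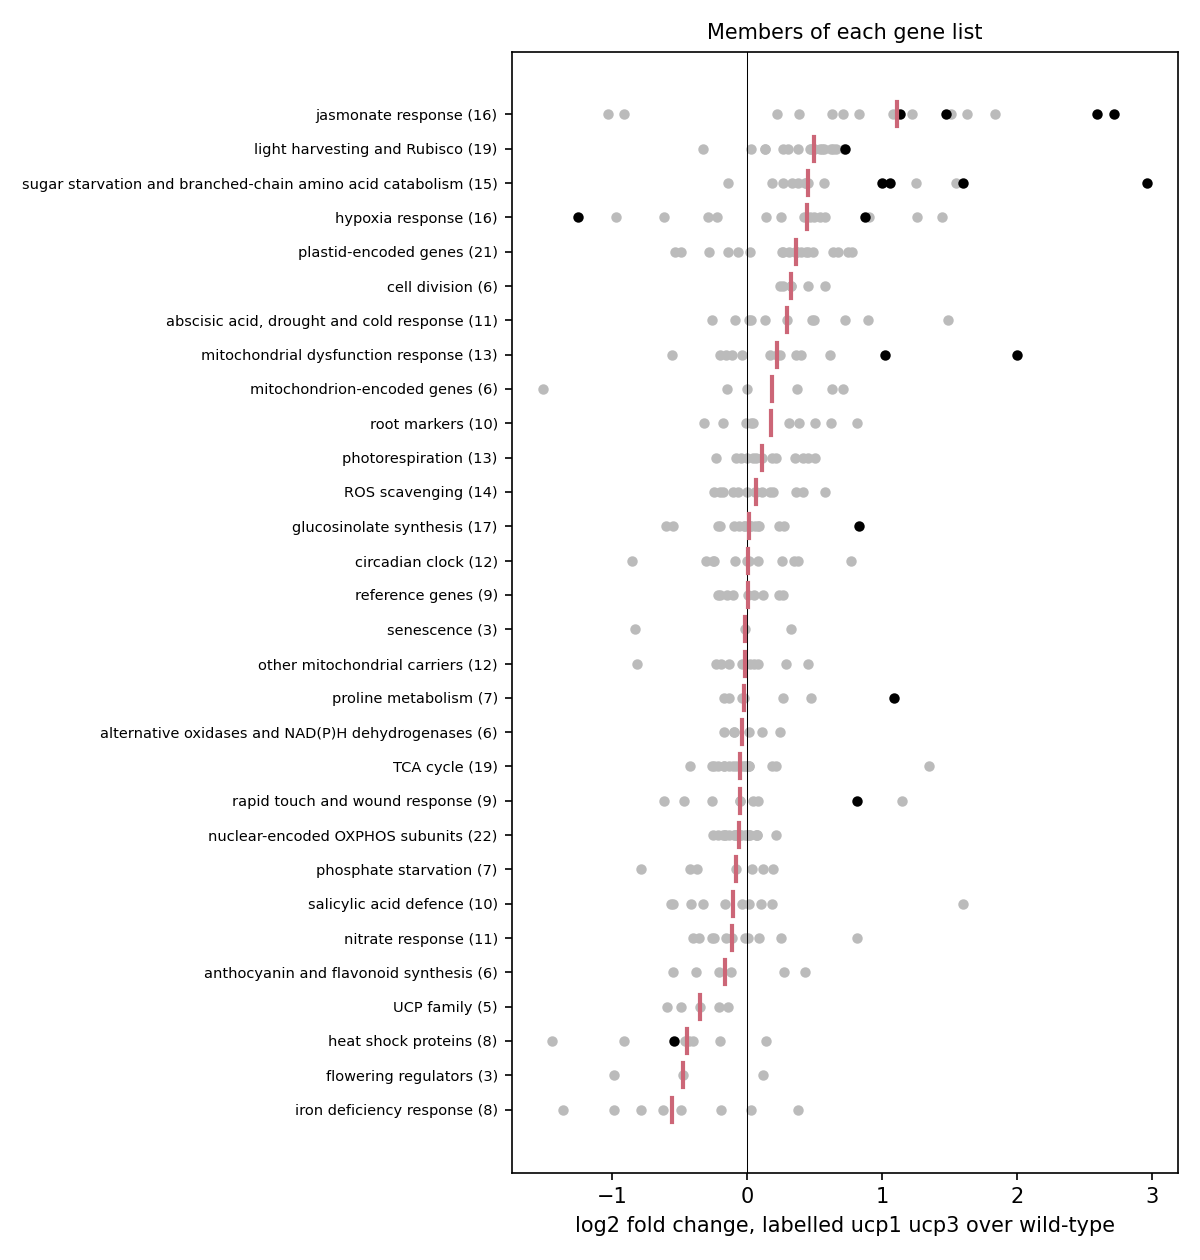
Log2 fold change (horizontal axis, libraries labelled ucp1 ucp3 over wild-type) of each tested member of the 30 lists tested, with the number of tested members in brackets. Black points passed the test over all genes, grey points did not, and the red line is the list's median, which runs from -0.56 for the iron deficiency list to 1.11 for the jasmonate list.

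Members passed in 5 lists that camera did not call. In the hypoxia response list of 16, HUP54 rose (72.9 ± 4.50 to 134 ± 4.92 CPM) and LBD41, a hypoxia-responsive transcription factor gene, fell (75.3 ± 4.13 to 28.8 ± 10.2 CPM), with a camera adjusted p of 0.0679 (0.786 with an estimated correlation); 5 of 16 alternatives called the list at the preset correlation, among them that without wild-type replicate 3, where 6 members rose. Adjusted over the list alone, 4 were higher, among them ADH1 (1.26), and 2 were lower, LBD41 and HRA1 (-0.97). In the mitochondrial dysfunction response list of 13, GSTU25 and the cytochrome P450 gene CYP81D8 (log2 fold change 1.02) rose, though 0 rose without wild-type replicate 1, without ucp1 ucp3 replicate 1 or without ucp1 ucp3 replicate 3, while AOX1A, which encodes the stress-inducible alternative oxidase, had 29.1 to 40.5 CPM in wild-type and 42.4 to 44.8 CPM in the labelled mutants (log2 fold change 0.25; edgeR adjusted p = 0.427). P5CS1, the gene of the first enzyme of proline synthesis, rose from 23.2 ± 0.965 to 53.5 ± 18.6 CPM and was the single proline metabolism gene of 7 to pass. CYP79B3, of indole glucosinolate synthesis, was the one of 17 glucosinolate genes to pass (0.83), and the calmodulin-like TCH3 the one of 9 touch and wound genes (0.81; 15.5% of its 31-mers lie on the opposite strand of other genes). Each of these 3 lists had 0 members past the test when some single libraries were left out: 2 for proline metabolism, 1 for glucosinolate synthesis and 4 for touch and wound genes. The camera direction differed from the sign of the median for proline metabolism (median -0.02, mean 0.21, direction up), touch and wound genes (-0.05, 0.07, up) and glucosinolate synthesis (median 0.01, direction down).

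No member passed over all genes in the other lists. Leaving out 1 library moved the median of the 22 lists not called by up to 0.390, and changed its sign in 13. Median log2 fold changes were -0.06 for 22 nuclear-encoded oxidative phosphorylation subunits, -0.05 for 19 TCA cycle genes, -0.04 for 6 alternative oxidases and NAD(P)H dehydrogenases, -0.02 for 12 other mitochondrial carriers and 0.18 for 6 mitochondrion-encoded genes. They were 0.11 for 13 photorespiration genes, 0.06 for 14 genes of reactive oxygen scavenging, -0.11 for 10 salicylic acid defence genes, -0.16 for 6 anthocyanin and flavonoid genes (with a camera direction of up), -0.11 for 11 nitrate response genes and -0.08 for 7 phosphate starvation genes. The 8 iron deficiency genes had a median of -0.56, with BTS (-0.79), FRO3 (-0.62) and NAS4 (-1.36) lower adjusted over the list alone. Camera did not call this list (adjusted p = 0.0821; adjusted p = 0.786 with an estimated correlation), but 9 of 16 alternatives did at the preset correlation, with adjusted p-values from 0.00251 to 0.626 over the 16; leaving out wild-type replicate 1 or 2, or ucp1 ucp3 replicate 1 or 3, gave such a call, and 3 members fell without wild-type replicate 2. Medians were 0.01 for 12 circadian clock genes, -0.47 for 3 flowering regulators, -0.01 for 3 senescence genes, 0.17 for 10 root markers and 0.01 for 9 reference genes. Adjusted over the list alone, mMDH1 of the TCA cycle (-0.42), ORE1 of the senescence list (-0.83) and ATMG00980 of the mitochondrion-encoded genes (-1.51) were lower and CAT3 of the scavenging list (0.58) was higher, while MYB28 (-0.60) and MYB51 (-0.55) of the glucosinolate list were lower. For floral and pollen markers 2 genes were tested, and for seed markers 0.

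Mitochondrial loci held 0.00657% ± 0.000585 of reads in wild-type and 0.00661% ± 0.00273 in the libraries labelled ucp1 ucp3 (SD, n = 3; exact two-sided permutation p = 1). Plastid loci held 0.0360% ± 0.00728 and 0.0407% ± 0.00840 (exact two-sided permutation p = 0.6). The smallest p that 3 against 3 libraries allow is 0.1.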

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

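Alternatives were fixed before the data were examined, except thinning to the depth of the shallowest library. The counts of 136 higher, 84 lower, 48 higher at least 2-fold and 24 lower at least 2-fold moved by over 1.5 times as follows. DESeq2 gave 234 higher and 150 lower; without a filter there were 267 higher, 223 lower and 40 lower at least 2-fold; thinning, with 13672 genes tested, gave 47 lower at least 2-fold and 5 called lists in place of 8. The cause was not tested, beyond the numbers of genes tested. Leaving out 1 library gave from 31 to 326 higher, 16 to 347 lower, 24 to 97 higher at least 2-fold and 8 to 100 lower at least 2-fold, with 5 libraries in each such fit. The highest counts came without ucp1 ucp3 replicate 2, and 195 of its 673 calls were among the 220. The replicate block gave 122 higher and 45 lower; samples with the same number did not deviate together (correlations across genes -0.0682, -0.0964 and -0.0111), and no sample correlated best with its own number, so the numbers were not taken to pair the samples. Over the 16 alternatives UCP1 ranged from -0.54 to -0.19 without a call and the number of called lists from 5 to 11; UCP3 ranged from -0.56 to -0.37 without a call in 15, since DESeq2 gave it no adjusted p. The sugar starvation, jasmonate, light-harvesting and heat shock lists were called in all 16 at the preset correlation, and 0 lists were called with an estimated correlation in any. Lists that gained calls were iron deficiency, hypoxia, photorespiration and touch; floral and pollen markers, with too few genes past the filter for the test, were called without it (7 genes, adjusted p = 0.0444). Named genes kept their side of the threshold in 351 refits, lost a call in 79 and reversed in 0; tests of the 30 lists were lost in 19, gained in 18 and reversed in 0. Organelle shares of TPM gave exact permutation p-values of 1 and 0.8. Depth limits low genes most in ucp1 ucp3 replicate 3, where 1 read is 0.903 CPM.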

Other observations

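The tests in this part were chosen after the results were seen, except the test of genes near UCP1 and UCP3. Process terms in the annotation notes of 8439 tested genes, 248 terms in all, were compared with the calls by one-sided hypergeometric tests with Benjamini-Hochberg adjustment. Among genes higher in the libraries labelled ucp1 ucp3, response to wounding held 5 called genes of 59 against 0.524 expected (adjusted p = 0.0414): JAZ10, OPR3, the jasmonate amidohydrolase gene IAR3, AT1G19660 and AT1G51400. Among the lower genes, response to heat held 4 of 52 against 0.283 expected (adjusted p = 0.0351), the cytosolic chaperone genes Hsp70-2, HSP81-3 and AT3G09440 and the mitochondrial mtHSC70-2. Processing of ribosomal RNA held 3 of 24 against 0.131 expected (adjusted p = 0.0351): FIB2, a fibrillarin gene of the nucleolus, AT4G04940 and AT5G08600. Of these genes, AT1G51400 has 70.6% and AT3G09440 17.0% of its 31-mers on the opposite strand of other genes, and HSP81-3 shares 35.8% and mtHSC70-2 19.0% on the same strand. With called genes that share at least 10% taken as not called, wounding (4 genes, adjusted p = 0.0712) and heat (1 gene, adjusted p = 1) did not pass, and processing of ribosomal RNA did (adjusted p = 0.0428).

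Other called genes, named after their values were seen, were abundant. The monosaccharide transporter gene STP1 went from 323 to 1086 CPM, the antenna gene LHB1B1 from 1655 to 4867 CPM, the myrosinase gene TGG2 from 177 to 457 CPM and the gibberellin-regulated GASA1 from 566 to 240 CPM. LHB1B1 shares 31-mers with LHB1B2 and has 20.6% of them on the opposite strand of other genes, so its reads are uncertain, and STP1 has 12.8% there. With only tested genes placed in locus order, called genes were neighbours in 9 pairs, against 2.79 on average in 10000 random draws (permutation test, one-sided p = 0.00240). Untested loci can lie between the genes of a pair. IAR3 and AT1G51790 (log2 fold changes 0.65 and -0.98) changed in opposite directions, as did AT1G69840 and NRT1:2 (0.76 and -0.54). AT1G51790 and NRT1:2 each stood in more than 1 pair. Among the pairs were the related neighbours LHB1B1 and LHB1B2, TGG1 and TGG2, and HRGP1 and AT3G54580, which can also share reads. NRT1:2 and NRT1.7, which share a family name, were both lower (log2 fold changes -0.54 and -0.70). The random draws did not allow for related neighbours, so they do not tell such pairs from other clustering. Of 299 tested genes within 100 locus positions of UCP1 or UCP3, 5 were called (1.67%, against 1.26% elsewhere; Fisher's exact test, two-sided p = 0.434). Windows of 50 and 200 positions gave Fisher's exact p = 0.130 and p = 1, and calls at an unadjusted p under 0.05 gave a Fisher's exact p of 0.694.

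Transcripts of UCP1 and UCP3 remained in every library labelled ucp1 ucp3. Reads shared with another gene are argued against, since at most 4.15% of the 31-mers of either gene occur in another gene's mRNA on either strand. If the alleles abolish the transcript, 1 wild-type library under a mutant label would leave the others near 0, but the lowest UCP1 level among the 3 labelled mutants was 66.0% of the wild-type mean. That value does not bear on alleles that leave transcript, nor on a group of 3 libraries with the wrong label. An insertion outside the counted part, or one that leaves a partial transcript, stays open, because values along the gene were not analysed here.

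The sugar starvation, light-harvesting and jasmonate lists were higher in the libraries labelled ucp1 ucp3. None of these calls held with an estimated correlation, a setting that also missed a simulated rise. If hours of difference in harvest time move abundant clock genes by more than 2-fold, they are argued against by the 95% bounds of the 7 clock genes at 50 CPM or more, which reached at most 0.61 on the log2 scale (TOC1). Of the 12 tested clock genes, those with a mean under 50 CPM, among them CCA1 and LHY, were not used. The interval of TOC1 lay above 0 (0.08 to 0.61), so a difference in harvest time that moves clock genes less stays open. A larger share of green tissue as the whole cause of the antenna rise would raise the Rubisco small subunit genes by about as much, but the median of these 4 was 0.0805 (SD 0.22) against 0.55 for the 14 antenna genes of the list. Summed, so that reads shared within the set do not matter, the 4 had 22758 ± 1089 CPM in wild-type and 23337 ± 1827 CPM in the labelled mutants (SD, n = 3), and the antenna genes with LHB1B1 and LHB1B2 47657 ± 3285 and 75577 ± 14313 CPM. Plastid-encoded genes were higher too (median 0.36, 16 of 21 above 0, camera adjusted p = 0.0166, and 0.786 with an estimated correlation). Polyadenylated libraries take organelle RNA to a varying extent, and plastid loci held 0.0360% of reads in wild-type and 0.0407% in the labelled mutants. These genes therefore did not decide, and a smaller contribution of green tissue stays open. The root markers, looked at before the Rubisco set was chosen, had a median of 0.17 with 7 of 10 above 0 and did not decide. Unequal depth as the source of these calls at the preset correlation is argued against by thinning, after which the highest camera adjusted p of the 3 lists was 1.4e-06. Thinning leaves the reads of labelled mutant 3, the shallowest library, as they were, so it does not test the weight of that library. Light, sugar supply or growth that differed between plates, which the labels do not record, and an effect of the mutations also stay open, so the source of the joint rise is not settled.

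Replicate 2 of the libraries labelled ucp1 ucp3 lay between the groups on the genes called without it. Across the 670 of these that were also tested with all 6 libraries, its median position was 0.460 on a log2 scale from 0 (wild-type mean) to 1 (mean of the other labelled mutants). The end at 1 includes labelled mutant 3, which lay apart on the first principal component. Values there were 59.3 for it, 9.42 for labelled mutant 1 and -1.26 for replicate 2. The position of replicate 2 therefore depends on labelled mutant 3. Genes chosen for a difference that leaves out a library can pull its position towards the other group. This choice as the whole cause is argued against, since labelled mutants 1 and 3, each left out in turn with the 670 genes of smallest p, had median positions of 0.899 (quartiles 0.594 and 1.22) and 1.23, and wild-type replicates 1 to 3 0.165, 0.351 and 0.0388. For labelled mutants 1 and 3 the mean at 1 included replicate 2, and a low replicate 2 raises their positions. The size of the gap to 0.460 is therefore not like for like. Over all genes, with no such choice of genes, the Spearman correlation of replicate 2 was 0.983, 0.982 and 0.974 with wild-type replicates 1 to 3 and 0.979 and 0.968 with labelled mutants 1 and 3. Labelled mutants 1 and 3 in turn correlated most with replicate 2, the deepest library. The shallowest, labelled mutant 3, correlated at only 0.940 to 0.968 with the other libraries. These correlations, not corrected for depth, therefore do not place replicate 2 nearer wild-type. Wild-type RNA mixed into that library would put its genes at 1 common mixture, with a best share of 48.2% from the other labelled mutants; 4.03% of the genes lay over 2 SD from it against 4.55% by chance, and 7.73% of the 194 genes changed at least 2-fold, so this explanation cannot be told apart from a weaker response of those plants. The 27 genes beyond 2 SD lay on both sides: 18 were nearer the other labelled mutants (position over 0.75), 6 nearer wild-type (under 0.25) and 3 between. Of the genes named here after their values were seen, LTP6 deviated most of all, with 30.9 CPM where the mixture predicts 15.1 CPM, SPPA had 17.8 CPM against 36.5 CPM, and PQL3 and CAX1, at positions -0.107 and -0.185, were at the wild-type level.

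Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 220 called genes, the labelled one, and the highest of the others gave 1. For genes changed at least 2-fold, 1 split gave as many as 72, and the highest of the others gave 1. For called lists, 2 splits gave as many as 8, and the splits other than the labelled one gave from 2 to 10. With 10 splits the share cannot fall under 0.05.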
